A study of Mus musculus with 4 samples.

How the data were processed

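Gene expression was measured in primary cultures of mouse cerebral cortex, from C57BL6 animals. There were 2 arrays of neuron cultures and 2 arrays of astrocyte cultures, which the titles label as biological replicates. Per the labels, neurons came from fetuses at embryonic day 16 and were moved to a medium with 1% fetal calf serum and 19.4 mM glucose. Astrocytes came from newborn animals and were grown in medium with 10% serum and 33 mM glucose. The series description gives 7 days in vitro for neurons and 20 days for astrocytes. The protocol text gives 1 common period for all assays, close to that of the neurons and shorter than that of the astrocytes. The series description was used here to describe the groups. Cell type therefore changed together with donor age, medium and, by the series description, time in culture, and the 4 arrays cannot separate these.

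Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 50 ng of RNA through 2 cycles of cDNA synthesis. The deposited values are probe set intensity values on a linear scale, which the authors computed with MAS5, per the submitters' processing notes. The version of that tool is not given in the sources used here. The values are whole numbers. The mean after trimming 2% from each end lay between 149.997 and 150.002 on each array, as a common scaling target gives. No detection calls were used here. Each array held 45101 probe sets, of which 64 were controls and 45037 measured transcripts. In the platform annotation 34945 of these had 1 gene symbol, 932 had several and 9160 had none; 34741 were matched to the gene table by Entrez identifier to update the symbol. No gene was named from a probe set with several symbols. Of 890 entries in the gene lists, 69 had no probe set of their own.

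Control probe sets were left out, and values were kept as scaled by the authors and transformed to log2(value + 12.5). The offset is the median over the 4 arrays of each array's 25th percentile, and it damps the noise of dim probe sets. Except where a fold is given as "at least", fold changes are on this scale and understate the change of dim genes. A probe set was kept where at least 2 of the 4 arrays lay at or above the array's median, which left 25019. Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. Every adjusted p of a gene is from this limma fit. The fit had 2 residual degrees of freedom and a prior worth 6.27. A gene was read by its kept probe set with the highest mean among those with 1 symbol, which gave 12040 genes. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.18.

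Background was taken from the 27 control probe sets for Bacillus subtilis transcripts, whose highest signals were 21 and 23 on the neuron arrays and 17 and 15 on the astrocyte arrays. The hybridization controls, such as bioB of Escherichia coli, which lay between 252 and 299, were not used for it. Where both arrays of a group lay at or under the background, the fold is given as "at least", against the mean of the array backgrounds. Such folds were computed from the signals without the offset. They can therefore exceed the fold on the offset scale, as for Calb1 (at least 70.3 against 45.4). The background rule was chosen after the control values were seen.

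Before the data were examined, 43 gene lists were fixed, 13 of cell type markers and 30 of functions, together with the filter, the offset, the test and the alternatives. The 41 lists with at least 5 measured genes were tested with limma's camera (preset correlation 0.01), adjusted over the lists. The erythroid and sex-linked lists had fewer measured genes and were not tested. An alternative estimated the correlation within each list, which leaves camera only the 2 residual degrees of freedom. It called 0 lists, although some had a negative estimate, such as the neuron markers (-0.032). It therefore cannot tell whether correlation within a list undoes a call. The genes named in the text were set by a rule fixed at the same time: the 8 named genes with the largest fold in each direction among those past the threshold with groups that do not overlap; from each list the 2 largest changes in its majority direction, the largest in the other direction and the member with the highest mean; Gfap, Tubb3, Aif1, Olig2, Col1a1 and Pecam1; and the monocarboxylate transporters and lactate dehydrogenases. Genes outside the rule are marked as chosen after their values were seen.

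The fit was tested on simulated data: 4 arrays were drawn for the 25019 probe sets, 200 of them changed. Means were as observed, and variances were drawn from the prior that the fit estimated. In this simulated comparison of neurons with astrocytes, 40.3% of the 2-fold changes and 100% of the 4-fold and 8-fold changes were recovered, and 2.44% of calls were false. In the data 57.2% of the kept probe sets passed, far more than were changed in the simulation, so the share recovered does not carry over. The false share was measured on variances of the kind the fit assumes. In a second simulation a shifted list was called, and 0 of 40 unchanged lists were. The simulated genes varied independently of each other, so this does not test lists whose genes vary together. The estimated correlation was 0.59 for the cell cycle list, for example. Alternatives changed the offset, the scaling between arrays, the filter, the trend, the probe sets used, the set test and the threshold, added the replicate number as a block, or left out each array in turn. Plots were drawn with matplotlib 3.10.9.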

Results

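The data are 4 arrays, 2 from cultures of mouse cortical neurons and 2 from cultures of mouse cortical astrocytes, and the single comparison the design implies is neurons against astrocytes. The replicates of a group were close to each other: the correlation of log2 values across probe sets was 0.980 for neurons and 0.983 for astrocytes, against 0.669 to 0.682 between the groups. Probe sets are not independent replicates. The share of probe sets above the highest Bacillus subtilis control was 63.1% and 61.4% on the neuron arrays and 66.5% and 66.9% on the astrocyte arrays. These shares use each array's own control, which was higher on the neuron arrays. At a signal of 100 or more the shares were 31.0% and 31.1% on the neuron arrays and 30.4% and 30.1% on the astrocyte arrays. The 3' to 5' signal ratio of Actb, a sign of RNA integrity, was 1.44, 1.49, 1.49 and 1.44, and that of Gapdh was 0.740, 0.773, 0.720 and 0.711.

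The cultures differed over most of the genes measured. Of 12040 genes, 7486 (62.2%) passed the threshold, 3737 of them higher in neurons and 3749 higher in astrocytes. At least 2-fold differences were found for 2169 genes higher in neurons and 2263 higher in astrocytes, and at least 8-fold differences for 468 and 322. The groups did not overlap in 81.9% of genes, where chance gives 33.3%. Of the genes higher in neurons, 374 were not above background in astrocytes, and 366 were the reverse, where the background was higher on the neuron arrays. Of 3611 called genes with more than 1 kept probe set, 151 had a probe set called in the other direction. With 1 array left out, the number higher in astrocytes lay between 2493 (without astrocytes replicate 2) and 2992.

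The genes with the largest excess in neurons included those for proteins of the synapse and of growing neurites. Snap25, a component of the complex that fuses synaptic vesicles, had a signal of 4087 ± 387 in neurons and 1.5 ± 0.707 in astrocytes (mean ± SD, n = 2 here and below), at least 255-fold higher (adjusted p = 9.81e-08). Dcx, a microtubule protein of young neurons, was at least 180-fold higher, Syt4 at least 200-fold, Stmn4 at least 140-fold, Tenm2 at least 121-fold, Gng4 at least 169-fold and the transcription factor gene Neurod6 at least 98.7-fold. Crmp1, which takes part in axon guidance, was 107-fold higher (3560 ± 204 against 21.0 ± 1.41). When all probe sets of a gene were averaged, the log2 fold change of Snap25 was 5.80, that of Dcx 5.10, that of Tenm2 5.24 and that of Gng4 3.93.

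In astrocytes the leading genes were Cp, which encodes the copper protein ceruloplasmin, and Anxa3, a calcium-dependent membrane-binding protein. Cp had a signal of 7676 ± 607 in astrocytes and 55.0 ± 66.5 in neurons, a 158-fold difference (adjusted p = 1.85e-05). Anxa3 was 124-fold higher, the organic anion transporter gene Slco1a4 119-fold, Elobl 100-fold, Fmod 83.9-fold, Ahnak 80.9-fold, the interferon-induced Ifitm3 74.7-fold and Ecrg4 74.7-fold. For most of these genes the neuron arrays differed from each other; Cp was at 8 in neurons replicate 1 and 102 in replicate 2. Without neurons replicate 1 the log2 fold change (neurons minus astrocytes) was -6.07 for Cp, -5.70 for Anxa3, -6.05 for Slco1a4, -5.78 for Elobl, -5.41 for Fmod, -5.70 for Ahnak and -5.48 for Ifitm3. Without neurons replicate 2 these were -8.55, -8.22, -7.74, -7.52, -7.37, -6.98 and -6.96. All stayed past the threshold in both fits. When all probe sets of a gene were averaged, the log2 fold change of Ahnak was -3.89, that of Cp -6.16, that of Fmod -5.68 and that of Ecrg4 -5.38.

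Neuronal markers separated the cultures. All 18 measured neuron markers were higher in neurons, with a median log2 fold change of 4.97; Tubb3, the neuronal beta-tubulin, was 38.0-fold higher (2948 ± 103 against 65.5 ± 3.54). Stmn2, the marker with the highest mean, was 3.96-fold higher in neurons and still had a signal of 1475 ± 14.1 in astrocytes. Of 13 excitatory neuron markers 11 were higher in neurons and 1, Nrn1, was higher in astrocytes; Bcl11b was 40.8-fold higher in neurons. Of 12 inhibitory neuron markers 11 were higher in neurons, among them Calb1 (at least 70.3-fold) and the somatostatin gene Sst (38.7-fold), and Npy was 2.58-fold higher in astrocytes. When probe sets were averaged, the log2 fold change of Calb1 was 3.15 (5.50 by its main probe set) and that of Bcl11b 4.25 (5.35); Bcl11b had 5.94 without astrocytes replicate 1 and 4.76 without replicate 2. Npy missed the threshold without neurons replicate 1 (adjusted p = 0.0682) and without astrocytes replicate 2 (adjusted p = 0.0946). Camera called the neuron markers (adjusted p = 2.21e-11), the excitatory markers (adjusted p = 7.26e-05) and the inhibitory markers (adjusted p = 6.27e-05), each with adjusted p = 0.231 with an estimated correlation. Adjusted over the list alone, the counts were the same 18, 11 and 11.

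**Figure D1:**
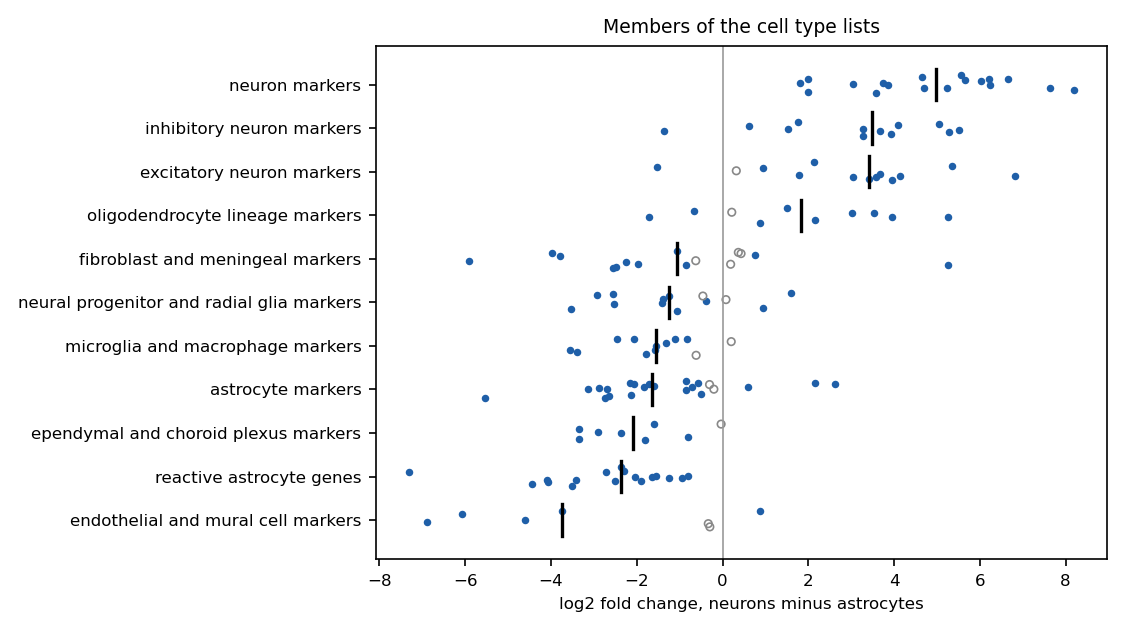
Log2 fold change (neurons minus astrocytes, x axis) of each measured member of the 11 tested cell type lists (rows). Filled points passed adjusted p 0.05 and open points did not, vertical bars are list medians, and points are spread vertically only for legibility; the medians ran from 4.97 for neuron markers to -3.75 for endothelial and mural markers.

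Astrocyte markers were mostly higher in astrocytes, but many were well above background in both cultures. Of 22 measured markers, 17 were higher in astrocytes, 3 were higher in neurons and 2 did not pass, with the same counts adjusted over the list alone (adjusted p = 0.000287; adjusted p = 0.231 with an estimated correlation). Gfap, the intermediate filament of astrocytes, was 46.3-fold higher in astrocytes (1939 ± 275 against 55.5 ± 75.7), and Mlc1 was 8.85-fold higher. Gfap was at 2 and 109 on the neuron arrays; its log2 fold change was -4.00 without neurons replicate 1 and -7.06 without replicate 2, and it missed the threshold without astrocytes replicate 1 (adjusted p = 0.0646) or 2 (adjusted p = 0.0721). Averaging its probe sets gave -3.67, and leaving out probe sets that match several transcripts gave -2.79. Apoe, which encodes the main apolipoprotein of brain, was 1.81-fold higher in astrocytes and had a signal of 3286 ± 150 in neurons. The 3 markers higher in neurons were Sparcl1 (6.18-fold) and, named after their values were seen, the glutamate transporter gene Slc1a2 (4.47-fold) and Aldoc (1.51-fold). All 17 measured reactive astrocyte genes were higher in astrocytes (camera adjusted p = 1.44e-06, and 0.231 with an estimated correlation). With any 1 array left out fewer passed, with list medians from -2.59 to -2.34. Vim was 5.16-fold higher in astrocytes. The receptor gene Osmr was 21.6-fold higher, with a log2 fold change of -2.86 when its probe sets were averaged, against -4.43.

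Markers of other cell types also differed. Only part of each list was measured: 12 of 20 microglia, 10 of 17 oligodendrocyte and 7 of 18 endothelial and mural markers. For fibroblast and meningeal markers this was 15 of 18, and for ependymal and choroid plexus markers 8 of 13. The rest were too dim to be tested or had no probe set of their own. Of 12 microglia and macrophage markers, 10 were higher in astrocytes (11 adjusted over the list alone; adjusted p = 0.00211, and adjusted p = 0.231 with an estimated correlation), at low signals: Ctss had 284 ± 16.3 against 15.5 ± 17.7, C1qa 140 ± 22.6 against 2.00 ± 0, and Csf1r 150 ± 1.41 against 43.5 ± 4.95. The log2 fold change of Ctss was -2.87 without neurons replicate 1 and -4.25 without replicate 2. Aif1 was too dim to be tested. Of 10 oligodendrocyte lineage markers 7 were higher in neurons, with Pdgfra, the receptor of oligodendrocyte precursors, 38.5-fold higher and the myelin gene Mbp 15.4-fold higher, while Cnp was 3.29-fold and Olig1 1.59-fold higher in astrocytes. Averaging probe sets gave log2 fold changes of 3.46 for Pdgfra (5.27 by its main probe set) and 3.08 for Mbp (3.94). Olig1 missed the threshold without any 1 of 3 arrays, with adjusted p = 0.134 without neurons replicate 2, 0.142 without astrocytes replicate 1 and 0.227 without astrocytes replicate 2, and also without the filter (0.0886) and without the mean-variance trend (0.0512). This list's test passed (adjusted p = 0.0384; adjusted p = 0.278 with an estimated correlation) but not with a filter at the 75th percentile (median log2 fold change 0.22 against 1.84, adjusted p = 0.514) or without neurons replicate 2 (adjusted p = 0.0555); 4 of its members were higher in neurons without neurons replicate 2, and 4 without astrocytes replicate 1. Olig2 did not pass the threshold (652 ± 14.8 in neurons, 562 ± 77.1 in astrocytes, adjusted p = 0.214).

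Of 7 measured endothelial and mural markers, of 18 fixed, 4 were higher in astrocytes and 1, Cspg4, was higher in neurons. The list missed the threshold in camera (adjusted p = 0.0507, and 0.528 with an estimated correlation). By camera it passed with an offset 4 times as large (adjusted p = 0.0299) and with quantile normalization (0.0460). It also passed without probe sets matching several transcripts (0.0488), with probe sets averaged (0.0463) and with either neuron array left out. With either astrocyte array left out it did not pass. The list median lay between -4.27 and -3.23 with 1 array left out. Cspg4 missed the threshold without neurons replicate 1 (adjusted p = 0.111) or 2 (0.0700), without astrocytes replicate 1 (0.0941) and without the filter (0.0512). Members of the list higher in astrocytes included Slco1a4 (119-fold) and 2 actin cytoskeleton genes of smooth muscle, Tagln (67.4-fold) and Acta2 (24.3-fold). The log2 fold change of Tagln was -4.81 without neurons replicate 1 and -7.34 without replicate 2; for Acta2 these were -3.65 and -5.56. Acta2 had -2.40 without probe sets that match several transcripts and -3.50 with its probe sets averaged, against -4.60. Pecam1 was too dim to be tested. Of 15 fibroblast and meningeal markers 9 were higher in astrocytes (10 adjusted over the list alone), led by Islr (60.2-fold) and Foxc1 (at least 15.8-fold). In neurons 2 were higher, among them Pdgfra (38.5-fold), which is also in the oligodendrocyte lineage list. Camera missed the threshold for this list (adjusted p = 0.0507, and 0.275 with an estimated correlation). The fibroblast list passed camera with an offset 4 times as large (adjusted p = 0.0416) and with quantile normalization (0.0498). It also passed without probe sets matching several transcripts (0.0344) and with probe sets averaged (0.0463). With 1 array left out it passed only where that array was neurons replicate 1, with list medians from -1.60 to -0.71. Col1a1 was at 72.0 ± 43.8 in astrocytes and 25.5 ± 2.12 in neurons (adjusted p = 0.0307), and missed the threshold without neurons replicate 1 or 2 or astrocytes replicate 2, and without the filter (adjusted p = 0.131). Of 8 ependymal and choroid plexus markers, 7 were higher in astrocytes (adjusted p = 0.00211; adjusted p = 0.231 with an estimated correlation), with Foxj1, the regulator of motile cilia, 10.1-fold and Dynlrb2 10.2-fold higher.

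Of 13 progenitor and radial glia markers 9 were higher in astrocytes and 2 in neurons, 1 of them with either astrocyte array left out (adjusted p = 0.0158; adjusted p = 0.231 with an estimated correlation). Nes was 11.6-fold and Pax6 7.57-fold higher in astrocytes, and Hes5 3.02-fold higher in neurons. Nes had a log2 fold change of -4.26 without neurons replicate 1 and -2.82 without replicate 2. Fabp7 was high in both cultures (8510 ± 149 and 8046 ± 148; adjusted p = 0.480). Of the cell cycle genes, 19 of 24 were higher in neurons and 2 in astrocytes (camera adjusted p = 0.000287, and 0.528 with an estimated correlation). With 1 array left out the list median lay between 1.24 and 1.68. Fewer members were then called higher in neurons, unless that array was neurons replicate 2. On the same arrays 7 of 10 oligodendrocyte lineage markers were higher in neurons and 2 in astrocytes. Which cells of the neuron cultures held the cell cycle transcripts was not tested. The proliferation antigen gene Mki67 was 14.3-fold higher in neurons (383 ± 120 against 14.5 ± 2.12) and Rrm2 4.44-fold higher, whereas Ccnd1, a cyclin of the G1 phase, was 13.9-fold higher in astrocytes (7769 ± 764 against 546 ± 44.5).

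Genes of neuronal signalling were higher in neurons as groups. All 24 genes of synaptic vesicles and release, 17 of 22 glutamate and GABA receptors, 19 of 20 voltage-gated channels and 23 of 27 axon growth genes were higher in neurons. Adjusted over the list alone these counts were 24, 18, 19 and 23. As fixed, the synaptic list shares Snap25, Syn1 and Syt1 with the neuron markers, and the axon list shares Gap43 and Stmn2 with them. Camera gave adjusted p = 1.83e-11, 1.65e-06, 1.20e-08 and 1.06e-07, and adjusted p = 0.231 with an estimated correlation for each. The receptor gene Grm5 was at least 75.6-fold higher, Gabrb2 41.6-fold, the potassium channel gene Kcnq3 at least 59.2-fold, the sodium channel gene Scn3a at least 27.3-fold and Gap43, a growth cone protein gene, 101-fold. Averaging probe sets gave log2 fold changes of 3.84 for Kcnq3 (5.95 by its main probe set) and 4.17 for Gabrb2 (5.38). Gria3 was 1.65-fold and Sema3c 2.05-fold higher in astrocytes, and Gria3 missed the threshold with any 1 array left out (adjusted p between 0.0511 and 0.186) and without the filter (adjusted p = 0.0619).

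**Figure D2:**
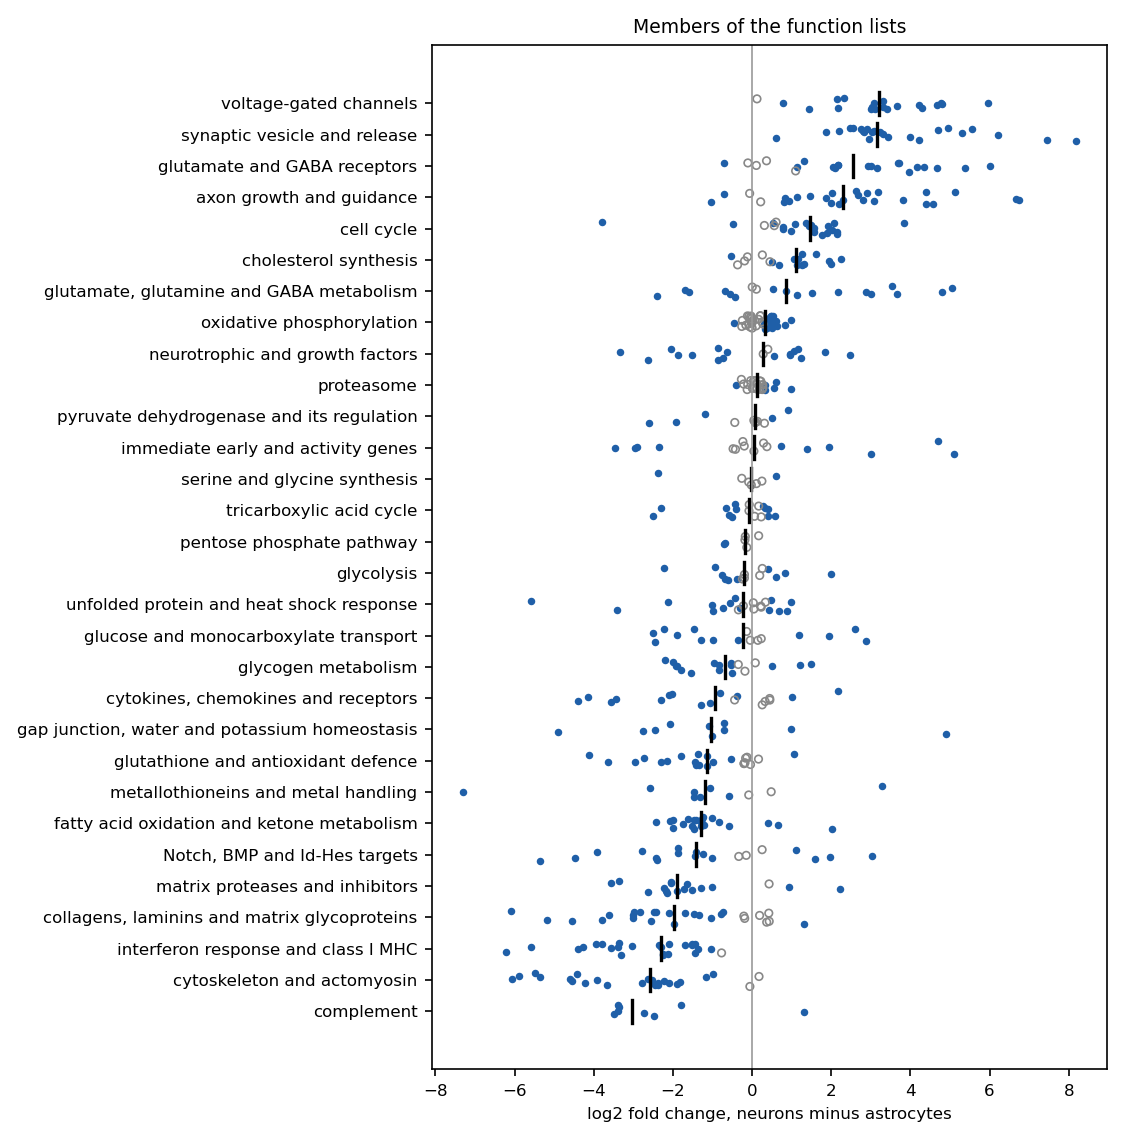
Log2 fold change (neurons minus astrocytes, x axis) of each measured member of the 30 function lists (rows). Filled points passed adjusted p 0.05 and open points did not, vertical bars are list medians, and points are spread vertically only for legibility; members of the glycolysis list (median -0.19) lay on both sides of 0, while 24 of 25 interferon and MHC genes were higher in astrocytes.

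Transcripts for the transport of glucose, lactate and pyruvate differed between the cultures in both directions, depending on the gene. Slc16a1, which encodes the monocarboxylate transporter MCT1, was 5.67-fold higher in astrocytes (3425 ± 94.0 against 594 ± 45.3), and the glucose transporter gene Slc2a1 was 5.46-fold higher (1325 ± 148 against 234 ± 48.1). Slc16a7, which encodes MCT2, was at least 7.17-fold higher in neurons (115 ± 15.6 against 5.00 ± 2.83). Ldhb was 3.75-fold higher in astrocytes (6487 ± 553 against 1720 ± 96.2), and Ldha was at 2506 ± 268 in neurons and 2265 ± 262 in astrocytes (adjusted p = 0.361). Slc16a3 was too dim to be tested. As a group the 16 transport genes did not pass (4 higher in neurons, 8 in astrocytes, adjusted p = 0.439), and 5 were higher in astrocytes without neurons replicate 2 or without astrocytes replicate 1. Nor did the 15 glycolysis genes (4 and 6, adjusted p = 0.574; 1 or 2 higher in neurons and 3 or 4 in astrocytes with 1 array left out), in which Hk2 was 4.68-fold higher in astrocytes and the enolase gene Eno2 4.00-fold higher in neurons. Pfkp was 1.93-fold higher in astrocytes by its main probe set, but averaging its probe sets gave a log2 fold change of -0.13 (adjusted p = 0.408).

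**Figure D3:**
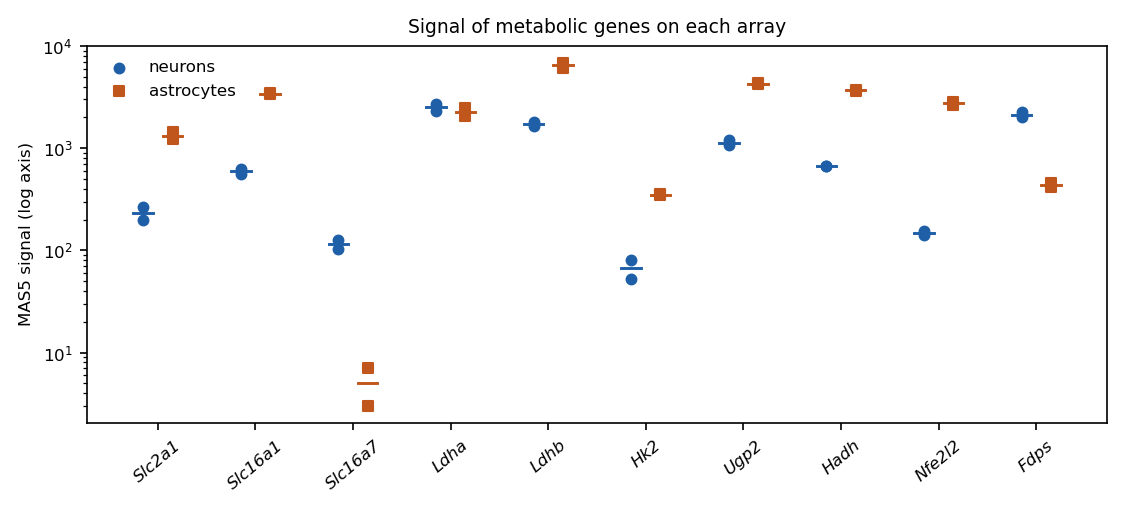
MAS5 signal (y axis, log scale) of 10 metabolic genes on each of the 2 neuron arrays (circles) and 2 astrocyte arrays (squares), with short lines at group means. Slc16a1 was at 594 in neurons and 3425 in astrocytes, while Ldha was at 2506 and 2265.

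Among mitochondrial pathways, 18 of 21 genes of fatty acid oxidation and ketone metabolism were higher in astrocytes and 3 in neurons (adjusted p = 8.32e-05; adjusted p = 0.231 with an estimated correlation). Hadh, an enzyme of beta-oxidation, was 5.40-fold and Hadhb 4.22-fold higher in astrocytes, and Bdh1, which interconverts ketone bodies, was 4.03-fold higher in neurons. With probe sets averaged their log2 fold changes were -1.76 (Hadh), -1.32 (Hadhb) and 2.88 (Bdh1). Of 45 oxidative phosphorylation genes 24 were higher in neurons and 1, Ndufa2, in astrocytes, by small amounts: the median log2 fold change was 0.32, and Atp5g1 had the largest at 0.99. Ndufa2 missed the threshold without neurons replicate 1 (adjusted p = 0.0518) or 2 (0.0674) and without astrocytes replicate 2 (0.0544). The oxidative phosphorylation list was called (adjusted p = 0.0158; adjusted p = 0.725 with an estimated correlation) but not without astrocytes replicate 1 (adjusted p = 0.0599) or by fry (adjusted p = 0.0804). With 1 array left out, 7 of its members were higher in neurons, or 14 where that array was astrocytes replicate 2. The tricarboxylic acid cycle genes went both ways (5 higher in neurons, 7 in astrocytes, adjusted p = 0.525), with Idh2 5.66-fold and Suclg2 4.91-fold higher in astrocytes and Cs 1.5-fold higher in neurons; with 1 array left out, 1 or 2 members were higher in neurons and 3 or 5 in astrocytes. The log2 fold change of Idh2 was -1.55 with its probe sets averaged, against -2.50, and that of Suclg2 -2.89 without probe sets matching several transcripts, against -2.29. Of 11 genes of pyruvate dehydrogenase and its regulation 2 were higher in neurons and 3 in astrocytes (adjusted p = 0.778; 1 and 2 without neurons replicate 2, 2 and 2 without astrocytes replicate 2); the kinase gene Pdk4 was 6.05-fold and the phosphatase gene Pdp1 3.77-fold higher in astrocytes, and the list median (0.08) and mean (-0.37) differed in sign.

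Glycogen metabolism genes were mostly higher in astrocytes (12 of 18, with 3 higher in neurons). Camera gave adjusted p = 0.0265, and 0.231 with an estimated correlation. With any 1 array left out fewer were called higher in astrocytes, with list medians from -0.76 to -0.64. Those higher in astrocytes included Phkb (4.62-fold), the branching enzyme gene Gbe1 (4.03-fold) and Ugp2 (3.76-fold), while Gsk3b was 2.79-fold higher in neurons. Cholesterol synthesis genes were mostly higher in neurons (12 of 18, with 1 higher in astrocytes; adjusted p = 0.00264; adjusted p = 0.276 with an estimated correlation), including Fdps (4.75-fold), Mvd (4.02-fold) and Hmgcs1 (2.21-fold). Sc5d, the exception, had 1 of its 3 kept probe sets called, and missed the threshold with 1 array left out in 3 of the 4 fits and with its probe sets averaged (log2 fold change -0.26 against -0.53, adjusted p = 0.107). Of 23 glutathione and antioxidant genes 15 were higher in astrocytes and 1 in neurons (camera adjusted p = 7.26e-05, and 0.231 with an estimated correlation). With any 1 array left out fewer were called higher in astrocytes, with list medians from -1.25 to -1.04. Nfe2l2, which encodes the regulator NRF2, was 17.3-fold and Gpx8 12.4-fold higher in astrocytes. The metallothionein and metal handling list missed the threshold in camera (adjusted p = 0.0641) but passed without the filter (0.0415). With 1 array left out it passed only where that array was neurons replicate 1, with list medians from -1.32 to -0.94. In the main fit 7 of 10 genes were higher in astrocytes, Mt3 among them (6.03-fold), and fewer were with either astrocyte array left out. The transferrin receptor gene Tfrc was 9.77-fold higher in neurons. Tfrc was also the only erythroid gene measured. The genes of glutamate, glutamine and GABA metabolism did not pass as a group (11 higher in neurons, 6 in astrocytes, adjusted p = 0.0678); Gad1, which makes GABA, was 33.3-fold higher in neurons (log2 fold change 3.88 with its probe sets averaged, against 5.06), and Pcx, pyruvate carboxylase, 5.32-fold higher in astrocytes. Neither the 6 pentose phosphate genes (0 and 2; 0 and 1 with any array left out; adjusted p = 0.402) nor the 7 serine and glycine synthesis genes (1 and 1; 0 and 1 with any array but neurons replicate 1 left out; adjusted p = 0.778) passed, although Gldc of the latter was 5.19-fold higher in astrocytes.

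Extracellular matrix, contractile and immune genes were higher in astrocytes as groups. This held for 20 of 27 collagens, laminins and matrix glycoproteins, 14 of 17 matrix proteases and inhibitors, 22 of 24 cytoskeleton and actomyosin genes, 24 of 25 interferon and class I MHC genes, 7 of 8 complement genes and 11 of 18 cytokine and receptor genes; the counts were the same adjusted over the list alone. Without astrocytes replicate 2, 13 of the collagens, laminins and glycoproteins were higher in astrocytes. Camera gave adjusted p = 6.27e-05, 0.000209, 2.93e-09, 2.93e-09, 0.00370 and 0.0179. The first 5 had adjusted p = 0.231 with an estimated correlation and the cytokine list adjusted p = 0.313 with an estimated correlation. Sparc was 12.2-fold higher (9451 ± 1106 against 762 ± 77.8), Col5a2 36.5-fold, Timp3 11.9-fold, Anxa1 59.1-fold, Ifit3 48.4-fold, B2m, the light chain of class I MHC, 10.6-fold and the growth factor gene Csf1 21.1-fold. With probe sets averaged the log2 fold change of Sparc was -2.66 (-3.61 by its main probe set) and that of Csf1 -2.57 (-4.40). On the same arrays 10 of 12 microglia and macrophage markers and 9 of 15 fibroblast and meningeal markers were higher in astrocytes. These lists share members as fixed, so they are not separate evidence. The fibroblast and collagen lists share Col1a1, Col1a2, Col3a1, Col6a1, Col6a2, Dcn and Fn1. The complement list shares C1qa, C1qb and C1qc with the microglia list, and C3 and Serping1 with the reactive astrocyte list. Of its 16 fixed genes, 8 were measured. Tagln and Acta2 are in the actomyosin and mural lists. The reactive astrocyte list also shares Vim with the actomyosin list, Gbp2 with the interferon list, Timp1 with the protease list and Cxcl10 with the cytokine list. The exceptions included Lamb1, Mmp24, Cd55 and Cx3cl1, each higher in neurons. Cx3cl1 missed the threshold without astrocytes replicate 1 (adjusted p = 0.0522) or 2 (adjusted p = 0.0524).

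Of 19 Notch, BMP and Id-Hes genes 12 were higher in astrocytes and 4 in neurons (adjusted p = 0.0106; adjusted p = 0.231 with an estimated correlation); Id3 was 41.1-fold and Id1 22.2-fold higher in astrocytes, and the Notch target Nrarp 8.11-fold higher in neurons (log2 fold change 1.90 with its probe sets averaged, against 3.02). Of 10 genes of gap junctions, water and potassium homeostasis 8 were higher in astrocytes (adjusted p = 0.0214; adjusted p = 0.231 with an estimated correlation), with the potassium channel gene Kcnj10 30.0-fold and the water channel gene Aqp4 6.71-fold higher. Slc12a5, which encodes the chloride exporter KCC2, was 29.9-fold higher in neurons. The gap junction list missed the threshold of camera without the filter on dim probe sets (adjusted p = 0.05002). As fixed, it shares Aqp4, Gja1, Gjb6 and Slc4a4 with the astrocyte markers, so it is not separate evidence from them. The Notch list likewise shares Hes1, Hes5 and Notch1 with the progenitor list. The growth factor list (8 higher in neurons, 9 in astrocytes, adjusted p = 0.708; median 0.28, mean -0.19) and the unfolded protein and heat shock list (5 and 9, adjusted p = 0.459) did not pass. Leaving out an astrocyte array left 4 or 5 growth factor genes higher in neurons and 5 in astrocytes, and leaving out neurons replicate 1 left 3 and 5 of the heat shock list, and replicate 2 left 3 and 6. Fgf1 was 10.0-fold and the small heat shock gene Hspb8 47.6-fold higher in astrocytes; the log2 fold change of Hspb8 was -3.59 with its probe sets averaged, against -5.57. Of 25 proteasome genes 5 were higher in neurons and 1 in astrocytes (2 and 0 adjusted over the list alone; adjusted p = 0.283). Adjusted over the list alone the unfolded protein list had 6 and 9, and the lists given above without such a count kept theirs. With 1 array left out, 1 or 2 proteasome genes were higher in neurons. Fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, also passed for 7 lists that camera did not call: fibroblast (adjusted p = 0.00185), glutamate metabolism (0.00206), growth factor (0.00311), tricarboxylic acid cycle (0.0138), heat shock (0.0244), endothelial and mural (0.0475) and metallothionein (0.0485).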

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

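All tests in this part were chosen after the result they concern was seen.

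The control probe set for the B1 repeat, which enters no comparison above, had a mean signal 1.93 times as high on the neuron arrays as on the astrocyte arrays (10049 ± 827 against 5196 ± 711, n = 2), far above the Bacillus subtilis controls; the B2 repeat control had 11225 ± 19.8 and 11294 ± 812. The middle control probe set for 18S ribosomal RNA had a mean 3.28 times as high on the astrocyte arrays as on the neuron arrays (3328 ± 1015 against 1015 ± 247, n = 2), while the 5' probe set had 6812 ± 1176 against 3719 ± 794 and the 3' probe set 4577 ± 1653 against 2484 ± 825.

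Astrocyte markers were well above background in the neuron cultures, at a median of 31.3% of their astrocyte level. Array background is argued against, since 19 of 22 measured markers lay above the highest Bacillus subtilis control on both neuron arrays. Carry-over of cells like those of the astrocyte cultures would bring all their abundant transcripts. Among 563 genes with a signal of at least 2000 in astrocytes, the 20th lowest had at most 2.72% of its astrocyte level in neurons, far below the median marker share, so such cells cannot be the whole source. Glial cells in another state, from a fetal donor and in a medium with less serum, stay open as an untested biological explanation.

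Genes of the astrocyte cultures were higher in neurons replicate 2 than in replicate 1. Of 39 genes with a signal of at least 2000 in astrocytes and under 5% of it in neurons, 36 were higher in replicate 2, with a median gain of 1.14% of the astrocyte level. A higher background over that whole array is argued against. The first quartile of signal was 13 in replicate 1 and 14 in replicate 2, against a median gain of 40 for these genes. The highest Bacillus subtilis control was at 21 and 23. The 15405 probe sets dim on all arrays had a median gain of 0, and 75% of them gained 5 or less. They were chosen under 30 on that array too, so they could not show a gain of 40. Carry-over of a small share of astrocyte-culture RNA or cells into neurons replicate 2 stays open: the gain of 1.14% is the pattern itself, measured on genes that include those it was seen on and between 2 single arrays, so it does not decide. Acta2 gained 5.87% and Kcnj10 had a difference of -0.942%. The labels give no difference in treatment between these replicates. As they are labelled biological replicates, a difference between the 2 cultures themselves also stays open and was not tested.

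The Y-linked gene Eif2s3y was at 3 on both astrocyte arrays and at 129 and 73 on the neuron arrays. The other Y-linked probe sets read were of Eif2s3y, Kdm5d and Uty. Ddx3y, also in the fixed list, had no probe set of its own. Of 8 other probe sets of Y-linked genes, 6 were lower on both astrocyte arrays than on both neuron arrays, where the share among other dim probe sets (24.4%) gives 1.96 (exact binomial test, one-sided, p = 0.00373); all lay near background, and those of 1 gene are not independent. Few or no male cells in the astrocyte cultures may give this, but Xist, which should then be higher in astrocytes, was at 3529 ± 426 there and 4180 ± 701 in neurons (adjusted p = 0.183). Lower expression in astrocytes cannot be told apart from it, because 0 of the other Y-linked probe sets reached 100 on both neuron arrays.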

How the results depend on the processing

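All alternatives here were fixed before the data were examined. Of 2214 values of 159 named genes under an alternative, 2128 kept direction and side of the threshold, 67 were no longer past it, 9 were newly past it and 10 reversed. The reversed values were all of genes that had not passed: Psma3 (log2 fold change -0.014 with quantile normalization, -0.037 with equal medians, -0.022 averaging probe sets, and -0.033 to 0.10 with 1 array left out), Tkt (0.035 without probe sets matching several transcripts, 0.38 averaging probe sets, and -0.51 to 0.15 with 1 array left out), Egr1 (-1.10 to 0.14 with 1 array left out) and Pdha1 (-0.17 averaging probe sets). The cause was not tested. With a filter at the 75th percentile 9422 probe sets passed, against 14303, 4769 of them higher in neurons, because fewer were tested. With 1 array left out, and the lone array taken to vary like the other group, 9524 to 10240 probe sets passed, 4440 to 5272 of them higher in astrocytes; 2493 to 2992 genes were higher in astrocytes. Of 27 lists called (11 higher in neurons, 16 in astrocytes), camera with an estimated correlation called 0 (0 and 0), with a smallest adjusted p of 0.231 on few residual degrees of freedom; fry called 33, and the other alternatives 23 to 30. The share of called genes higher in neurons lay between 46.1% and 51.7%.

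Replicate numbers were not shown to pair the arrays (correlation of replicate differences across probe sets -0.090). With the replicate number as a block, 7404 genes passed, 7276 of them among the 7486 called without it, and 30 lists, the endothelial and mural (adjusted p = 0.0156), fibroblast (0.0245) and metallothionein (0.0342) lists being newly called. The offset acts most on dim genes. With it left out, or 4 times as large, 7245 and 7617 genes passed, but these totals do not show dim genes apart. The folds of called named genes moved by over 1.5 times, or the call ended, for 39 genes with no offset, 55 with the larger offset and 33 with probe sets averaged.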

Other observations

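Activity genes did not pass as a group between the cultures, but single members differed strongly and in both directions. Of 17 immediate early and activity genes 6 were higher in neurons and 4 in astrocytes (adjusted p = 0.778). Nr4a3 was 34.5-fold higher in neurons (1004 ± 55.9 against 17.0 ± 2.83) and Egr3 at least 35.8-fold higher, while Fos was 11.1-fold higher in astrocytes (870 ± 103 against 67.5 ± 12). Egr1 was at 486 ± 287 in neurons and 624 ± 48.8 in astrocytes (adjusted p = 0.25).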
